A study of Homo sapiens with 30 samples.

How the data were processed

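Gene expression was measured in human blood monocytes on 30 single-colour Affymetrix human genome arrays, 1 array per sample. Per the labels' protocols, monocytes were purified by negative selection from buffy coats to a purity of at least 97%. They were held overnight with macrophage colony-stimulating factor at 100 ng/ml in medium with 10% serum, which was lowered to 0.5% for the assay, with 0.5% dimethyl sulfoxide as vehicle. The series design names 5 donors. Cells received a small-molecule inhibitor (SMI) of the kinase Tpl-2 at 2.8 µM, an SMI of the kinase MEK at 0.31 µM or neither, for 1 h per the series design (the treatment protocol says at least 30 min). Lipopolysaccharide (LPS), a bacterial cell wall product, was then added at 10 ng/ml or left out, and cells were harvested 6 h later. Each of the 6 groups held 5 arrays numbered 1 to 5 in the labels. Each inhibitor was used at 1 dose.

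The deposited table held 19944 probe sets and 30 arrays with 0 missing values. Per the submitters' processing notes, the authors used RMA and limma, and versions were not stated there. Which background, summary and filter settings were used, and how the probe sets of the table were chosen, is not given in the sources used here. The deposited values were intensities on a linear scale, not log values: the lowest value per array was 3.97 to 4.67, the median 48.5 to 52.9 and the highest 23720 to 35100. The log2 of each deposited intensity was taken before any test, and no array was scaled further. On the log2 scale the array medians ran from 5.60 to 5.73. For arrays, their number per group limits the precision, and no read depth applies.

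Probe sets were named through the platform annotation supplied with the series. Of the 19944 probe sets, 18530 had 1 gene symbol, 278 had several and 1136 had none, and those with several or none were left unnamed. Of the symbols, 18498 matched the RefSeq gene table of assembly GRCh38.p14 by gene ID and 0 needed updating. The build behind the array's own design is not given in the sources used here, so no coordinates are printed. Left out were 4 control probe sets and 31 probe sets of XIST and Y-linked genes. The probe set with the highest mean over all arrays stood for each of the 64 genes that had more than 1, which left 18435 genes.

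Group means of log2 intensity were compared with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3. All 6 groups shared 1 estimate of the spread with 24 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with 0.05 as the threshold, and every adjusted p of a gene below comes from that limma fit unless another is named. A gene was called LPS-induced when it passed the threshold with a log2 fold change of at least 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

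The replicate numbers paired the arrays. Deviations from the group means correlated at 0.333 or more in each of the 75 pairs of arrays that shared a number (median 0.606), against at most 0.280 for arrays of different number (median -0.149). All 30 arrays correlated best with an array of their own number. The labels do not say that a number marks a donor, so the pairing rests on this check of the data. No pair of arrays held identical values, and correlations within a group ran from 0.948 to 0.990. The comparison without a term for the number was fixed as the main one, since the sources name none. A fit with the replicate number as a block (20 residual degrees of freedom) was the alternative, and its value stands beside a gene or list result where it changed the call or moved a count of calls by more than 1.5 times.

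Before the data were examined, the comparisons, the classes of LPS-induced genes, the rule for named genes, the gene lists and the alternatives were fixed. Named genes were, per main comparison, the 12 largest rises and 12 largest falls among genes past the threshold with the same sign in all 5 same-numbered pairs. For the other comparisons 6 each way were taken, and for each class of LPS-induced genes the 10 with the largest direct difference between the inhibitors. Members of the lists are named where their list is described, and the kinases of the Tpl-2 and MEK pathway list always.

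The 28 lists were inflammatory cytokines, chemokines, NF-κB feedback and target genes, ERK pathway output genes, MAPK phosphatases, Tpl-2 and MEK pathway components, negative regulators of cytokine signalling, interferon response, MHC class II antigen presentation, monocyte and macrophage surface and scavenger genes, prostaglandin and leukotriene synthesis, proteases with coagulation and matrix remodelling, cholesterol synthesis and uptake, lipid efflux and LXR target genes, glycolysis, lysosome, metallothioneins, heat shock, ATF4 and unfolded protein response, NRF2 and antioxidant genes, cell cycle, and markers of T cells, B cells, NK cells, platelets, neutrophils, erythroid cells and dendritic cells. They were tested in 9 comparisons with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Fry asks whether the genes of a list moved, on balance, 1 way, and compares them with no other genes. A list is said to have passed where it did so by camera at the preset correlation, unless another test is named. Of the 252 tests, 55 passed at the preset correlation, 13 with an estimated one and 74 at the preset correlation with the replicate block. A list's median, mean and test differed in sign in 42 of the 252 tests, 0 of them past the threshold.

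The code was first tested on simulated data with known changes, drawn from the LPS means, the replicate-number deviations and the residual spread of these arrays, for the comparison of Tpl-2 SMI + LPS with LPS over 18435 genes. Of 50 genes changed at each size, 22% were recovered at a log2 change of 0.5, 90% at 1, 94% at 1.5 and 98% at 2, with 2 false calls. With the replicate block the shares were 52%, 94%, 100% and 98%, with 8 false calls. A shift of 0.5 put into 1 of the 28 lists was found at the preset correlation (adjusted p = 1.02e-11) but missed with an estimated one (adjusted p = 0.264, estimated correlation 0.419). With the replicate block the estimated correlation was -0.000571 and the shift was found (adjusted p = 2.68e-07). The shifted list was glycolysis, in 1 simulated draw. Without the block, the estimated correlation thus missed a shift of this size in that list. Its power for other lists was not tested, and some lists with smaller medians passed with it below.

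The alternatives were the replicate block, a filter on dim genes, the mean of a gene's probe sets, each probe set tested on its own, quantile normalization again, median centring, eBayes with trend and robust options, array weights, the compared groups alone, and leaving out each array or each replicate number. Arrays or numbers were left out without the block, unless the block is named. Regroupings of the arrays, up to 100 per comparison, tested whether chance could give as many genes. Because both inhibitors were compared with the same LPS arrays, unchanged groups and an LPS group that they shared were simulated. This was done 100 times for the correlation and 20 times for the shared genes. The LPS arrays were also split in 20 ways, each inhibitor being compared with the LPS arrays of its own replicate numbers. The same splits were made of simulated unchanged groups that carried the number deviations of these arrays.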

Results

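The data were 30 arrays of human blood monocytes in 6 groups of 5: untreated cells, cells with a Tpl-2 inhibitor (Tpl-2 SMI), cells with a MEK inhibitor (MEK SMI), cells with LPS, and LPS-treated cells with either inhibitor. Tpl-2, encoded by MAP3K8, is a kinase that activates MEK, which in turn activates the kinases ERK1 and ERK2, after Toll-like receptors sense LPS. The series asks which signalling events downstream of Tpl-2 depend on MEK and which do not. Values below are log2 intensities or differences of them, and n = 5 arrays per group throughout.

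LPS separated the arrays first and the replicate number second. The first principal component carried 61.8% of the variance, and stimulation accounted for 97.5% of its spread. The second carried 11.7%, with 97.7% of its spread between replicate numbers. The 75th percentile of log2 intensity was 7.67 ± 0.03 (SD) in untreated cells and 7.38 ± 0.08 in LPS-treated cells, with medians of 5.67 and 5.64.

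**Figure D1:**
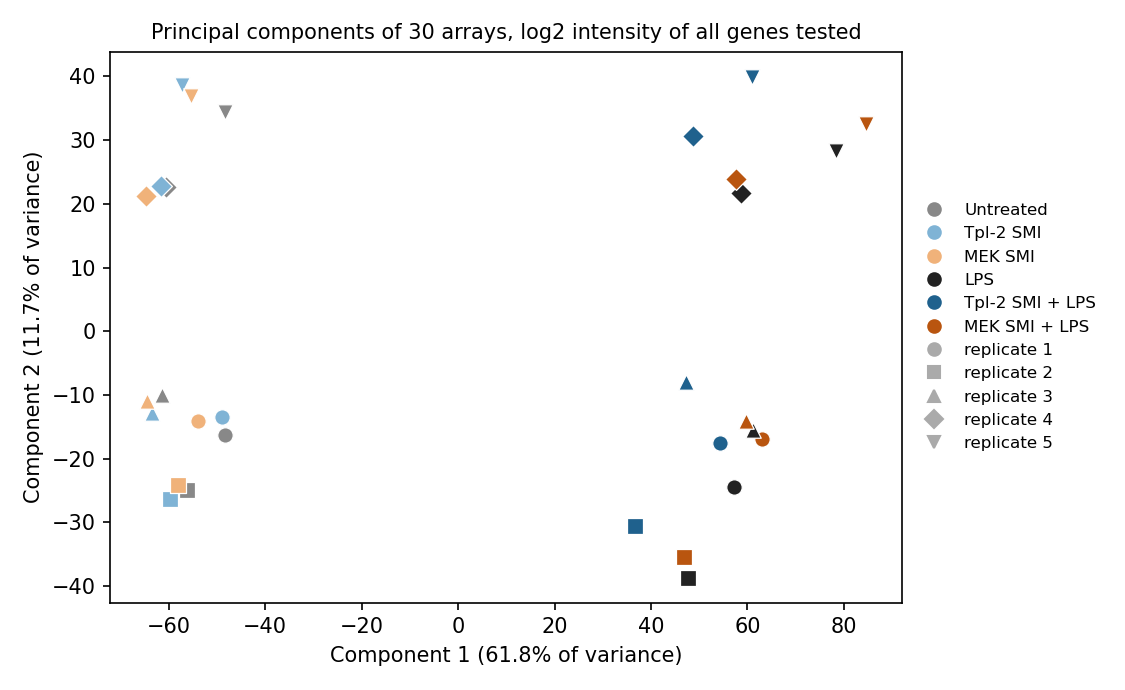
Scores of the 30 arrays on the first 2 principal components of log2 intensity (unitless scores, with 61.8% and 11.7% of the variance), coloured by group and shaped by replicate number. All arrays without LPS lie at negative and all arrays with LPS at positive scores on component 1, and on component 2 all arrays numbered 1 to 3 lie at negative and all numbered 4 or 5 at positive scores.

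LPS raised 27 of 28 inflammatory cytokine genes (camera adjusted p = 1.57e-17), and PTGFRN, CCR2 and FUCA1 led the falls. IL12B, the p40 subunit of interleukin-12 and interleukin-23, went from 2.86 ± 0.13 in untreated cells to 12.17 ± 1.44 with LPS, a log2 fold change of 9.31 (SE 0.57, adjusted p = 3.81e-13). Its untreated level lay below 3.31, the level under which 10% of genes lay, so this fold is a lower bound. IL6 rose by 8.86, INHBA, an activin subunit, by 8.23, ACOD1, the enzyme that makes itaconate, by 7.89, and PTGS2, the inducible cyclooxygenase, by 7.82. PTGFRN fell from 10.16 ± 0.27 to 3.62 ± 0.31 (log2 fold change -6.54). CCR2, the receptor for the chemokine CCL2, changed by -5.40, the scavenger receptor CD36 by -5.22, the adhesion molecule PECAM1 by -5.18 and fibronectin (FN1) by -4.58. In all, 8677 of 18435 genes changed, 4025 up and 4652 down, of which 1010 rose and 1830 fell at least 2-fold. The other leading rises were TNIP3 (7.82), ITGB8 (7.79), MIR3945HG (7.75), IL1A (7.64), CXCL1 (7.53), GJB2 (7.51) and tissue factor, F3 (7.49). The other leading falls were FUCA1 (-5.31), FGL2 (-4.71), TMT1A (-4.65), MNDA (-4.40), LINC01094 (-4.40), CYBRD1 (-4.37) and PDK4 (-4.31). Over these 24 genes the SE ran from 0.21 to 1.04 and the adjusted p from 3.61e-19 to 0.00101.

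Most cytokine, chemokine and NF-κB target genes rose with LPS. Of 28 inflammatory cytokines 27 rose and 0 fell (median 4.17, camera adjusted p = 1.57e-17), including IL10 (4.82), IL1B (4.62) and TNF (4.55). Of 26 chemokines 18 rose and 0 fell (1 fell with the replicate block; median 2.51, adjusted p = 8.91e-10). Beside CXCL1 these rises included CCL20 (7.03), CXCL5 (6.31), CXCL3 (6.04) and CCL2 (4.78). Of 26 NF-κB feedback and target genes 24 rose and 0 fell (median 2.01, adjusted p = 1.46e-20), among them TNFAIP3 (3.24) and ICAM1 (2.74). Of 20 genes of the ATF4 and unfolded protein response 18 rose (median 1.71, adjusted p = 4.32e-10), with DNAJB9 at 3.48, ASNS at 3.34 and XBP1 at 3.17. Of 11 MAPK phosphatases 7 rose and 2 fell (median 1.07, adjusted p = 0.0106), with DUSP4 at 3.45. These 5 calls held with an estimated correlation, at adjusted p = 0.000524 for cytokines and chemokines, 0.000686 for NF-κB genes, 0.0160 for the ATF4 list and 0.0241 for the phosphatases. Adjusted over the list alone, all 26 NF-κB genes rose and the other counts were the same.

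Of 28 ERK pathway output genes, those known to follow ERK activity, 16 rose and 2 fell (median 0.56, camera adjusted p = 0.000104). The call was lost with adjusted p = 0.0847 with an estimated correlation. PHLDA1 rose by 3.55, PLAUR, the urokinase receptor, by 3.39 and EGR3 by 3.00, while SPRED1 (-1.24) and HMGA1 (-1.27) fell. Metallothioneins (6 of 7 rose, median 1.77, adjusted p = 0.0127, MT2A 2.60), NRF2 and antioxidant genes (8 of 12 rose, 1 fell, 2 with the replicate block, median 1.08, adjusted p = 0.00614, NQO1 2.69 and HMOX1 -1.99) and heat shock genes (7 of 9 rose, median 0.78, adjusted p = 0.0193) passed at the preset correlation. They did not with an estimated correlation (adjusted p = 0.567, 0.434 and 0.458). Of 24 genes for proteases, coagulation and matrix remodelling 11 rose and 4 fell (median 0.65, adjusted p = 0.0183). That call was lost with an estimated correlation (adjusted p = 0.285) and kept when the replicate block was added (adjusted p = 0.0221). Adjusted over the list alone, 5 rather than 4 of these fell, and the other 4 lists kept their counts.

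More surface and antigen presentation genes fell than rose, and their lists passed camera only with the replicate block. Of 31 monocyte and macrophage surface and scavenger genes 5 rose and 14 fell (median -0.70, camera adjusted p = 0.0545, 0.0242 with the block and 0.535 with an estimated correlation). The scavenger receptor MSR1 changed by -3.83, CX3CR1 by -3.29 and the growth factor receptor CSF1R by -3.25, while the chemokine receptor CCR7 rose by 2.03. Of 13 genes of MHC class II antigen presentation 1 rose, the costimulatory ligand CD80 (4.67), and 7 fell (1 and 8 adjusted over the list alone, 2 and 10 with the block). Their median was -0.75, with adjusted p = 0.0880, 0.0258 with the block and 0.726 with an estimated correlation. Their list mean changed by -0.44 and that of the dendritic cell markers by -0.77, each lower in 5 of 5 same-numbered pairs. HLA-DMB changed by -2.04 and CIITA, the master regulator of the class, by -1.78. Members went both ways in prostaglandin and leukotriene synthesis (6 of 18 rose and 6 fell, ALOX5 -3.81 and LTA4H -3.71), negative regulators of cytokine signalling (7 of 17 rose and 6 fell, SOCS3 4.76, SOCS1 3.76 and ZFP36L2 -3.54) and cholesterol synthesis and uptake (4 of 16 rose and 4 fell, LSS 2.73, INSIG1 2.69 and HMGCS1 2.18).

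Further lists did not pass with LPS: lysosome (4 of 18 up and 9 down, CTSB -2.0), lipid efflux and LXR target genes (2 of 11 up and 3 down), glycolysis (2 of 17 up and 4 down, PFKFB3 3.08), cell cycle (5 of 30 up and 8 down, 9 and 10 with the replicate block, MCM5 -1.99) and interferon response. Of the 36 interferon response genes 7 rose and 2 fell, or 4 and 1 adjusted over the list alone, and 14 and 3 with the replicate block. For the cell cycle and LXR lists the median differed in sign from the mean or the test. For the other cell types, 2 of 8 B cell markers rose, 1 of 13 T cell markers (IL7R) rose, 1 of 6 erythroid markers rose (0 adjusted over the list alone), 4 of 9 dendritic cell and 2 of 13 neutrophil markers fell, and 0 of 10 NK cell and 0 of 9 platelet markers changed. The replicate block gave 3 rises and 1 fall among NK cell, 2 rises among platelet, 2 rises and 3 falls among neutrophil and 2 rises among T cell markers. None of these 7 lists passed camera. The dendritic cell list passed fry (adjusted p = 0.000912), and with the block all but the T cell list did (adjusted p from 2.52e-07 to 0.0311). Except where another number is given, the counts adjusted over the list alone equalled those over all genes, and the signs of median and mean or test differed for the neutrophil and T cell markers.

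In the Tpl-2 and MEK pathway itself, 7 of 17 measured components rose with LPS and 8 fell (8 and 8 adjusted over the list alone). MAP3K8 rose from 8.97 ± 0.35 to 12.59 ± 0.56 (log2 fold change 3.62, adjusted p = 6.43e-14). Its binding partners NFKB1 and TNIP2 rose by 2.52 and 1.09, MAP2K1, which encodes MEK1, by 0.93, RPS6KA3 by 0.84, MAPK8 by 0.77 and ARAF by 0.56. Lower were MAP2K2 (-0.37), IKBKB (-0.51), KSR1 (-0.58), MKNK1 (-0.74), MAPK3 (-0.82), MKNK2 (-0.92), RPS6KA1 (-1.39) and RPS6KA2 (-1.55). MAP2K6, at 0.40, and MAP2K4 did not pass, MAP2K6 passing with the replicate block. The list's median (-0.09) and mean (0.22) differed in sign, and the list did not pass.

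In LPS-treated cells the Tpl-2 inhibitor changed 535 genes, with falls led by TFPI2, F3 and IL24 and rises led by CLEC12B and RARRES1. TFPI2, a protease inhibitor, stood at 8.86 ± 1.93 with LPS and 4.63 ± 0.88 with the inhibitor as well (log2 fold change -4.23, SE 0.63, adjusted p = 0.000226). F3 changed by -3.75, IL24 by -3.73, the neutrophil chemokine CXCL5 by -3.50, the metalloproteinase MMP10 by -3.33, the TNF family ligand TNFSF15 by -3.27 and HBEGF, a ligand of the EGF receptor, by -2.96. CLEC12B, a C-type lectin receptor, rose from 4.02 ± 0.52 to 6.6 ± 0.29 (2.58, SE 0.44, adjusted p = 0.00106). RARRES1 rose by 2.45, SYNPO2 by 2.42, IL18 by 2.00 and MSMO1, a sterol oxidase of cholesterol synthesis, by 1.93. Of the 535 genes 262 rose and 273 fell, and 59 rose and 84 fell at least 2-fold (111 and 124 with the replicate block). Further rises were GPC4 (1.88), complement factor B, CFB (1.76), SLC1A3 (1.69), BCL2L14 (1.64), E2F7 (1.58), MAGI3 (1.51) and PRRG4 (1.47). Further falls were CEMIP (-2.58), CXCL6 (-2.56), SCG5 (-2.41), EGR3 (-2.40) and ASPH (-2.31). Over the 24 genes the SE ran from 0.27 to 0.90 and the adjusted p from 1.19e-05 to 0.0417. Adding the replicate block gave 2231 genes, 1253 up and 978 down, and leaving out the fourth Tpl-2 SMI + LPS array gave 338. Of the 24 genes 11 lost the call without 1 of the replicate numbers, among them CXCL5 and MMP10 (adjusted p up to 0.214 and 0.123).

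Among the gene lists, ERK output and cholesterol synthesis moved with the Tpl-2 inhibitor in LPS under both correlation settings. Of 28 ERK output genes 0 rose and 6 fell (11 fell adjusted over the list alone, 14 with the replicate block), with a median of -0.38. The camera adjusted p was 5.90e-09, and 0.0254 with an estimated correlation. PHLDA1 changed by -2.09, the ERK phosphatase DUSP6 by -2.04, DUSP4 by -1.49, PLAUR by -1.16 and SPRY2 by -0.67. Of 16 genes of cholesterol synthesis and uptake 6 rose and 0 fell (7 and 0 adjusted over the list alone, 6 and 1 with the block), with a median of 0.32. Their adjusted p was 2.38e-07, 0.0254 with an estimated correlation and 0.0621 with an estimated correlation and the block. After MSMO1 came SC5D (1.25), SQLE (1.06), LSS (0.78), IDI1 (0.64) and FDPS (0.62). Of 11 lipid efflux and LXR target genes 0 rose and 2 fell, ABCG1 (-1.35) and MYLIP (-1.19), with 3 falls adjusted over the list alone, and 2 rises and 3 falls with the block. That list did not pass (median -0.09, adjusted p = 0.259).

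Cytokine and chemokine genes fell in part. Of 28 inflammatory cytokines 1 rose and 7 fell (1 and 11 adjusted over the list alone, 3 and 12 with the replicate block; median -0.58, camera adjusted p = 1.79e-06, and 0.0617 with an estimated correlation). The falls were led by IL24 (-3.73), TNFSF15 (-3.27) and HBEGF (-2.96). After them came IL19 (-2.30), CSF3 (-2.04), IL20 (-1.75) and INHBA (-1.17). Of 26 chemokines 0 rose and 4 fell (1 and 5 adjusted over the list alone, 2 and 6 with the block; median -0.26, adjusted p = 0.0211, and 0.196 with an estimated correlation), including CXCL3 (-1.85) and CXCL2 (-1.41). The MAPK phosphatases passed too (1 rose and 3 fell, also adjusted over the list alone, 2 and 4 with the block; median -0.38, adjusted p = 0.0316, and 0.0965 with an estimated correlation), with DUSP2 at -0.90 and DUSP10 at 0.86. Of 18 prostaglandin and leukotriene genes PTGS2 fell (-1.20) and the receptor PTGER4 rose (1.08), or 3 rose and 1 fell adjusted over the list alone, as with the block. The NF-κB list did not pass (median 0.03), with 0 of 26 members changed, or 4 up and 1 down with the block.

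Stress response lists passed camera at the preset correlation and not with an estimated one. They were the ATF4 and unfolded protein response (2 of 20 fell, 4 adjusted over the list alone, 6 with the replicate block; median -0.27, camera adjusted p = 0.000746, and 0.263 with an estimated correlation), with TRIB3 at -1.32 and the cystine transporter SLC7A11 at -1.12. NRF2 and antioxidant genes (1 of 12 fell, also adjusted over the list alone, 6 with the block; median -0.43, adjusted p = 0.000746) and heat shock genes (0 of 9 changed, 4 fell adjusted over the list alone, 1 rose and 5 fell with the block; median -0.49, adjusted p = 0.0199) had adjusted p = 0.268 and 0.371 with an estimated correlation. By fry the ATF4 and NRF2 lists passed (adjusted p = 0.0349 and 0.0359) and the heat shock list did not (adjusted p = 0.0865). Of the 24 protease, coagulation and matrix genes 3 fell, also adjusted over the list alone, while 2 rose and 7 fell with the block. Their median was -0.14 and their adjusted p 0.0215, with 0.268 with an estimated correlation and 0.0164 with an estimated correlation and the block. Interferon response genes shifted upward as a list (median 0.42, adjusted p = 0.000834, 0.730 with an estimated correlation and 0.480 by fry), although 0 of 36 passed singly, also adjusted over the list alone, and 6 rose with the block. Among the lysosomal genes the cathepsin CTSL (-1.66) and NPC1 (-0.70) fell and ATP6V1H (0.72) rose, and adjusted over the list alone, as with the block, 8 of 18 rose and 3 fell. The lysosome list (median 0.36) and the metallothioneins (median 0.33, 0 of 7 changed) passed with the block only, at adjusted p = 0.0382 and 0.0170. MHC class II genes had a median of 0.18 (adjusted p = 0.0486, and 0.623 with an estimated correlation) with 0 of 13 changed, also adjusted over the list alone, and 2 up with the block. Their list mean was higher by 0.21 in 5 of 5 same-numbered pairs, and so was that of the dendritic cell markers, which share no gene with the list, by 0.20 (fry with the block, adjusted p = 0.0370). Single members passed in lists that did not: PFKFB3 of the glycolysis list (-0.55; 1 up and 2 down with the block), TLR2 of the surface list (-0.84; 2 down adjusted over the list alone, 4 up and 5 down with the block), and CISH (-1.0) and IL10RA (0.56) of the negative regulators (1 up and 2 down adjusted over the list alone, 2 and 2 with the block). None of the 17 pathway components passed, also adjusted over the list alone, while MAP3K8 (0.61), RPS6KA2 (0.64), MKNK2 (-0.36) and MAP2K1 (-0.24) did with the block.

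The MEK inhibitor changed 672 genes of LPS-treated cells, with falls led by TNFSF15, TFPI2 and CXCL5 and rises led by ENPP2 and HAMP. TNFSF15 went from 11.53 ± 0.83 with LPS to 7.0 ± 0.84 with the inhibitor as well (log2 fold change -4.52, SE 0.44, adjusted p = 2.76e-07). TFPI2 changed by -4.44, CXCL5 by -4.40, F3 by -3.83, EGR3 by -3.71, MMP10 by -3.53, EGR1 by -3.44 and DUSP6 by -3.07. ENPP2, which encodes the enzyme autotaxin, rose from 8.22 ± 0.87 to 10.90 ± 1.38 (2.69, SE 0.51, adjusted p = 0.00175). HAMP, which encodes the iron-regulating peptide hepcidin, rose by 2.32, CFB by 2.17 and GPC4 by 2.10. TLR8 and TLR7, receptors for single-stranded RNA, rose by 1.76 and 1.74. Of the 672 genes 219 rose and 453 fell, and 58 rose and 124 fell at least 2-fold (133 and 159 with the replicate block). Further rises were BCL2L14 (2.01), RARRES1 (1.97), C22orf42 (1.89), E2F7 (1.77), RASSF4 (1.72) and the chemokine CCL18 (1.72). Further falls were HBEGF (-2.93), SCG5 (-2.81), PHLDA1 (-2.77) and ASPH (-2.70). Over the 24 genes the SE ran from 0.27 to 0.90 and the adjusted p from 2.76e-07 to 0.0331. Adding the replicate block gave 2291 genes, 946 up and 1345 down. Without 1 of the replicate numbers 7 of the 24 genes lost the call, among them CXCL5, MMP10, TLR7 and TLR8 (adjusted p up to 0.0578, 0.0900, 0.226 and 0.0588).

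ERK output was the list with the lowest median in this comparison. Of its 28 genes 0 rose and 8 fell (13 fell adjusted over the list alone, 15 with the replicate block), with a median of -0.55. The camera adjusted p was 1.26e-11, and 0.00709 with an estimated correlation. After EGR3, EGR1, DUSP6 and PHLDA1 came SPRED1 (-2.11), DUSP4 (-1.49), SPRY2 (-1.02) and PLAUR (-0.94). Of 28 inflammatory cytokines 1 rose, IL18 (1.17), and 4 fell (2 and 10 adjusted over the list alone, 2 and 10 with the block; median -0.40, adjusted p = 0.000227, and 0.336 with an estimated correlation), including IL24 (-2.65) and CSF3 (-1.24). Of 26 chemokines 2 rose and 4 fell (3 and 8 adjusted over the list alone, 5 and 9 with the block; median -0.01, adjusted p = 0.205). The falls included CCL7 (-2.55), CXCL3 (-2.42) and CXCL2 (-1.50), and the rises were CCL18 and CCL19 (1.09). TNF (-1.30) and IL1A (-1.27) passed with the block only.

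Interferon response genes were the list with the highest median in this comparison (0.70, camera adjusted p = 5.23e-10). The call was lost with an estimated correlation (adjusted p = 0.582, and 0.257 with the block) and by fry (adjusted p = 0.213). Singly 0 of 36 passed, also adjusted over the list alone, while 18 rose with the replicate block, with GBP1 at 1.67, IFI27 at 1.44, GBP4 at 1.30, IFIT2 at 1.23 and RSAD2 at 1.18. Metallothioneins (0 of 7 passed, also adjusted over the list alone, 5 rose with the block; median 0.61, adjusted p = 0.0242) and the ATF4 and unfolded protein response (0 rose and 3 of 20 fell, 1 and 3 adjusted over the list alone, 1 and 9 with the block; median -0.33, adjusted p = 0.000247) had adjusted p = 0.606 and 0.377 with an estimated correlation. TRIB3 changed by -2.51, SESN2 by -0.55 and DDIT3 by -0.52. Of the 24 protease, coagulation and matrix genes 4 fell, among them the urokinase PLAU (-1.03), or 1 rose and 6 fell adjusted over the list alone, and 3 and 8 with the block. That list's median was -0.12 and its adjusted p 0.0242, and 0.377 with an estimated correlation. In cholesterol synthesis and uptake LSS rose (0.82) and STARD4 fell (-1.65), with 2 falls adjusted over the list alone and 3 with the block, and the list did not pass (median -0.07). Its list mean differed by -0.17, lower in 5 of 5 same-numbered pairs. Of the NF-κB list TNFAIP2 (0.96) and RELA (0.45) rose and IRAK3 (-0.50) fell, also adjusted over the list alone, with 5 up and 1 down with the block. Its adjusted p was 0.128, and 0.0272 with the block. The MHC class II list also passed with the block only (median 0.14, adjusted p = 0.0445), with CD80 (0.91) the 1 member that rose, or 2 with the block, beside a dendritic cell marker mean higher by 0.15 in 5 of 5 pairs. Of the 31 surface and scavenger genes TLR7 and TLR8 rose and TLR2 fell (-0.82), or 4 rose and 4 fell adjusted over the list alone, and 6 and 6 with the block. Of the 17 negative regulators ZFP36 (0.60) and IL10RA (0.57) rose and CISH (-0.83) and SOCS4 (-0.41) fell, or 4 and 2 adjusted over the list alone, and 4 and 3 with the block. In the MAPK phosphatases DUSP3 rose (0.78; 2 up with the block) and DUSP4 and DUSP6 fell. The lysosomal CTSL (-1.27) and NPC1 (-1.07) fell, with 1 up and 3 down with the block, as did the glucose transporter SLC2A3 (-2.05), with 2 down with the block. Single rises were NR1H3, which encodes LXRα (1.08; 3 up with the block), PTGER4 (0.88; 3 up with the block) and the heat shock gene DNAJA1 (0.64; 3 of that list fell adjusted over the list alone). The NRF2 list held 0 changes, and 1 rise and 4 falls with the block. Its list mean was lower (-0.24) and that of the LXR list higher (0.23), each in 5 of 5 same-numbered pairs. None of these 9 lists passed. MAP2K1 (-0.40) was the 1 pathway component that passed (1 rose and 1 fell adjusted over the list alone), while MAP3K8 (0.61) and RPS6KA3 (-0.64) did with the block. With either inhibitor in LPS 0 of 30 cell cycle genes changed (1 up and 1 down with the MEK inhibitor and the block), and of the 7 marker lists of other cell types 0 passed camera and 0 members changed. Adjusted over the list alone, as with the block, 1 dendritic cell marker rose with each inhibitor. The block also gave 1 fall of a neutrophil marker with each and of 1 NK cell and 1 platelet marker with the Tpl-2 inhibitor. Under the block, fry passed the neutrophil, platelet, NK cell and dendritic cell markers with the Tpl-2 inhibitor (adjusted p = 0.00985, 0.00985, 0.0487 and 0.0370) and 0 of the 7 lists with the MEK inhibitor. Their list means differed by -0.24, -0.13, -0.11 and 0.20 with the Tpl-2 inhibitor, each in 1 direction in 5 of 5 same-numbered pairs. With the MEK inhibitor the neutrophil mean was lower (-0.21) and the dendritic cell and NK cell means were higher (0.15 and 0.05), each in 5 of 5 pairs.

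**Figure D2:**
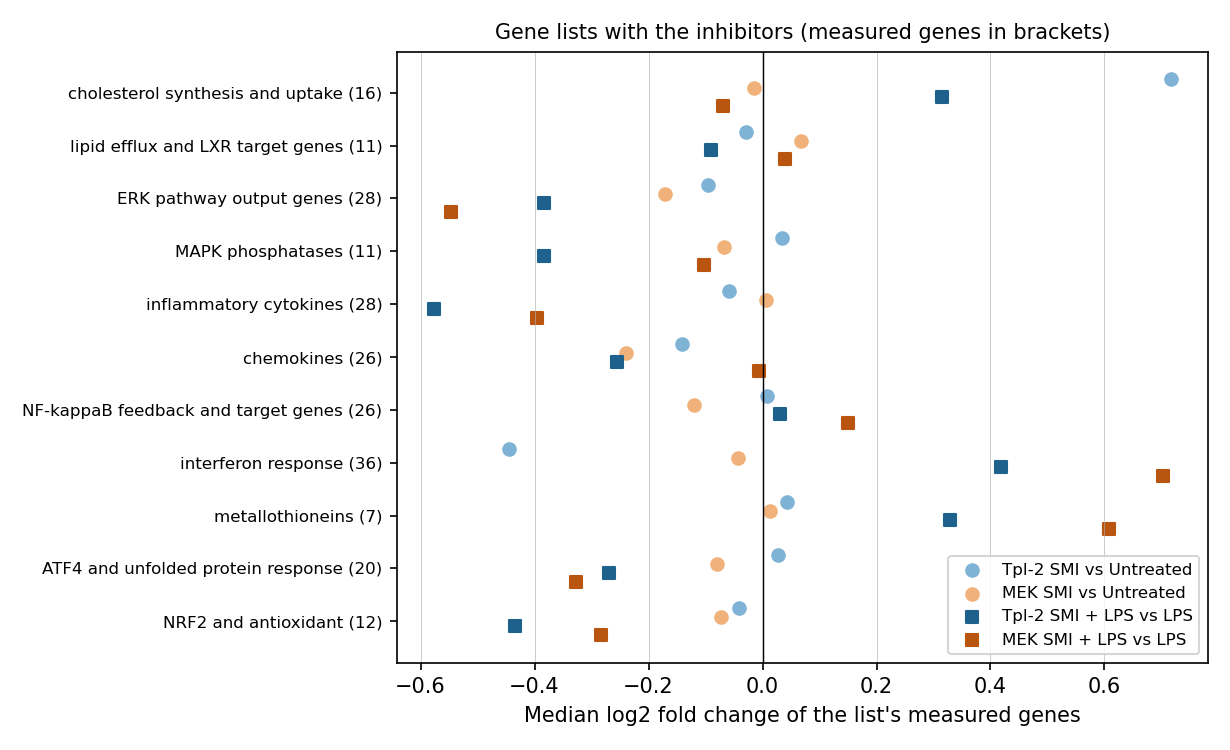
Median log2 fold change (horizontal axis, log2 units) of 11 gene lists for each inhibitor against its control, without LPS (circles) and with LPS (squares), with the number of measured genes in brackets. Cholesterol synthesis lies at 0.72 and 0.32 with the Tpl-2 inhibitor and at -0.02 and -0.07 with the MEK inhibitor, and ERK output with LPS lies at -0.38 and -0.55.

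Compared directly in LPS-treated cells, the inhibitors differed in 156 genes, with MSMO1 leading those higher with the Tpl-2 inhibitor. MSMO1 stood at 9.77 ± 0.38 with the Tpl-2 inhibitor and 7.34 ± 0.50 with the MEK inhibitor (log2 difference 2.43). Higher with the Tpl-2 inhibitor were also SLC25A40 (1.91), the cholesterol ester hydrolase NCEH1 (1.88), SQLE (1.70), SC5D (1.63) and SPRED1 (1.35), an inhibitor of signalling to ERK. IL19, a cytokine of the interleukin-10 family, stood at 8.22 ± 1.58 and 10.47 ± 1.09 (-2.25), with 10.52 ± 1.14 for LPS alone. Its call (adjusted p = 0.0477, 0.00162 with the replicate block) was lost when quantile normalized again, with trend and robust options, with array weights (adjusted p = 0.0546, 0.0554 and 0.0504) and without any 1 of the replicate numbers 2 to 5 (adjusted p from 0.126 to 0.254). Also lower with the Tpl-2 inhibitor were the transcription factors HES1 (-2.07) and INSM1 (-2.07), the cholesterol exporter ABCG1 (-2.06), CEMIP (-1.92) and HAMP (-1.92). Of the 156 genes 123 were higher and 33 lower with the Tpl-2 inhibitor. Further genes on the higher side were TMEM87B (1.35), SGK1 (1.30), JAKMIP2 (1.29), ZNF106 (1.29), ARL11 (1.28) and UTP25 (1.23). On the lower side were C22orf42 (-1.53), MYLIP (-1.44), which targets the LDL receptor for degradation, ARNT2 (-1.36), SOCS2 (-1.31), DUSP1 (-1.25) and RND1 (-1.23). The SE ran from 0.14 to 0.56 and the adjusted p from 1.04e-06 to 0.0477 over these 24 genes. Adding the replicate block gave 1253 genes, 942 higher and 311 lower. Without the third Tpl-2 SMI + LPS array 58 did, without the third MEK SMI + LPS array 90, and without the fifth Tpl-2 SMI + LPS array 97. Of the 24 genes 19 lost the call without 1 of the replicate numbers, and MSMO1, SLC25A40, SQLE, SC5D and MYLIP did not.

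Cholesterol synthesis and uptake was the 1 list that differed under every correlation setting (5 of 16 higher with the Tpl-2 inhibitor and 0 lower, 9 and 0 adjusted over the list alone, 8 and 0 with the replicate block). Its median was 0.40, with camera adjusted p = 2.68e-11, and 0.00486 with an estimated correlation. Of 11 lipid efflux and LXR target genes 0 were higher and 2 lower (0 and 3 adjusted over the list alone, 1 and 3 with the block; median -0.30, adjusted p = 0.0119). With an estimated correlation the adjusted p was 0.158, and 0.0420 with the block. The interferon list was lower with the Tpl-2 inhibitor (median -0.31, adjusted p = 0.0119, and 0.975 with an estimated correlation), with 0 of 36 genes past the threshold, also adjusted over the list alone. Of the ERK output genes SPRED1 was higher and JUNB lower (-0.50), or 5 and 1 adjusted over the list alone, as with the block, and the list did not pass (median 0.06, adjusted p = 0.317). The phosphatases DUSP1 and DUSP2 (-0.83) and the cytokine regulators SOCS2 and ZFP36 (-0.65) were lower with the Tpl-2 inhibitor, and with the block 1 phosphatase was higher and 3 phosphatases and 4 regulators were lower. Of 18 lysosomal genes 1 was higher and 0 lower, or 4 and 1 adjusted over the list alone and 5 and 1 with the block. The NRF2 list passed with the block only (median -0.26, adjusted p = 0.0159). Among pathway components RPS6KA2 (0.49) and MKNK2 (-0.50) passed with the block only. Under the block fry passed the NK cell and platelet markers (adjusted p = 0.0189 and 0.0366), whose list means differed by -0.16 and -0.12, lower with the Tpl-2 inhibitor in 5 of 5 pairs each. The inhibitors were compared at 1 dose each, 2.8 and 0.31 µM.

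Of the 1010 LPS-induced genes, 133 (13.2%) were lowered by the Tpl-2 inhibitor, 143 (14.2%) by the MEK inhibitor, 88 by both and 188 by either. The numbers were 309, 288, 207 and 390 of 1043 when the replicate block was added. Genes picked for high LPS arrays and set against the same arrays favour falls. Chosen on replicates 1 and 2 and tested on 3 to 5, with fewer arrays in each step, 65 and 57 of 840 were lowered (7.74% and 6.79%). Lower with the Tpl-2 inhibitor than with the MEK inhibitor by the direct test were 7 genes: IL19, HES1, CEMIP, HLX, NABP1, DUSP2 and ETS2, with direct differences from -2.25 to -0.66. Lower with the MEK inhibitor than with the Tpl-2 inhibitor were 5: JAKMIP2 (1.29), TRIB3 (1.20), PLAU (1.11), TRMT6 (1.06) and RILPL2 (0.53). Leaving out 1 of the replicate numbers ended the direct call of all 7 (adjusted p up to 0.274) and of 3 of the 5, JAKMIP2, TRIB3 and PLAU (adjusted p up to 0.322), and, besides the losses of IL19 given with its levels, array weights ended that of ETS2 (adjusted p = 0.0634) and quantile normalization again that of JAKMIP2 (adjusted p = 0.0531). With the block all 7 and all 5 passed the direct test, and these classes held 58 and 44 genes. No direct difference of the 7 or the 5 turned sign in these settings. A further 86 genes (173 with the block) were lowered by both and did not pass the direct test, and 90 were lowered by 1 inhibitor only without passing it. The first of these sets included EGR3, TNFSF15, IL24, CXCL5, CSF3, PHLDA1, SOWAHC, MAFF, TSPYL5 and CXCL3. The second included EGR1, STARD4, HECW2, CDC42EP3, PNPLA1, NT5E and F8, lowered by the MEK inhibitor, and BABAM2-AS1, ELL2 and TRIB1, lowered by the Tpl-2 inhibitor. With the block 4 of the 10 genes named from the first set (EGR3, TNFSF15, SOWAHC and TSPYL5) passed the direct test, as did 9 of the 10 named from the other, all but NT5E. Neither inhibitor lowered 822, among them INSM1, ARNT2, SLAMF1, THBS1, CXCL13, TNFRSF21, SLC16A10 and CHI3L2 and, raised by the MEK inhibitor, HAMP and C22orf42. With the block all 10 genes named from this set passed the direct test, against 4 without it (INSM1, ARNT2, HAMP and C22orf42). The median part of the LPS rise that was removed was 12.6% with the Tpl-2 inhibitor and 6.09% with the MEK inhibitor over all 1010 genes, and 43.0% and 46.6% over the 188. The 188 were taken for their fall with an inhibitor, which by itself favours a large part. The rise also uses the same LPS arrays as the fall. Induced genes raised further numbered 30 with the Tpl-2 inhibitor and 51 with the MEK inhibitor (112 and 158 with the block).

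**Figure D3:**
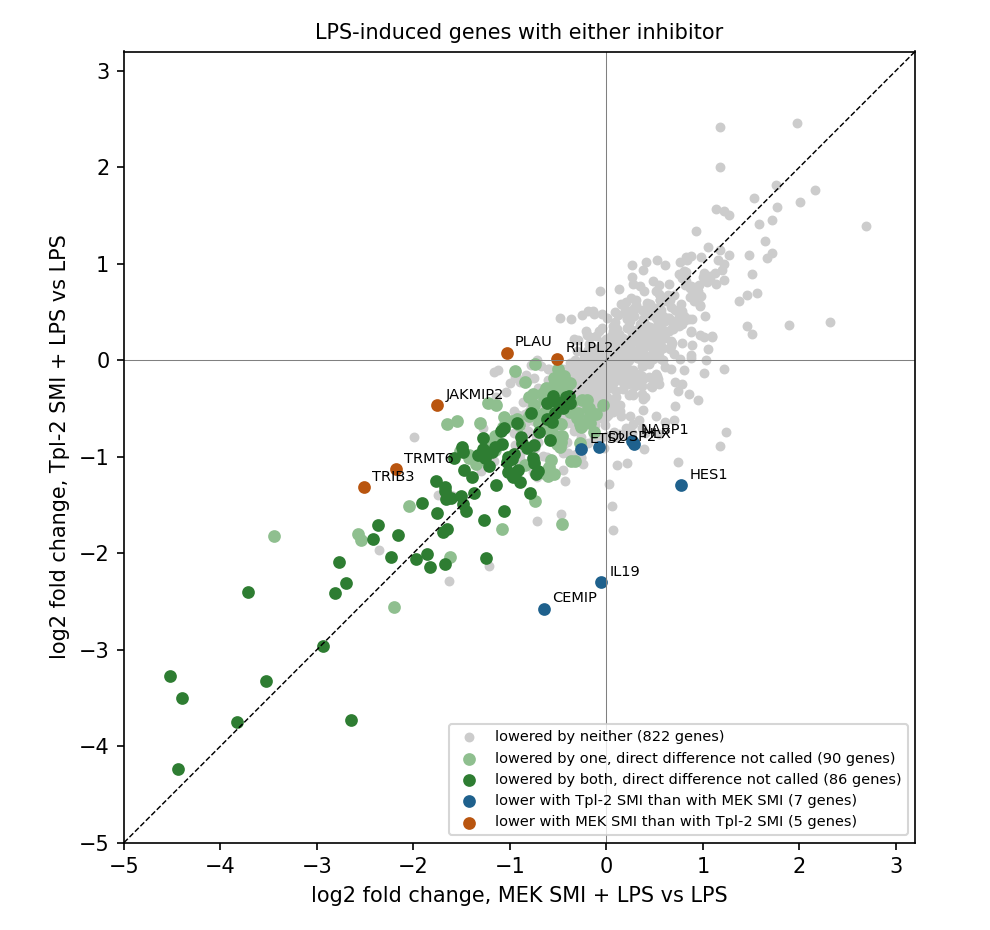
Log2 fold change with the MEK inhibitor (horizontal axis) against that with the Tpl-2 inhibitor (vertical axis) for the 1010 LPS-induced genes, each a point coloured by class, with the line of equal effects dashed. The 7 genes lower with the Tpl-2 inhibitor lie below the line and the 5 lower with the MEK inhibitor above it.

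Across all 18435 genes the inhibitors' effects in LPS correlated, with Pearson's r = 0.697 and Spearman's rho = 0.543. Genes are not independent replicates, and both effects use the same LPS arrays. Simulated unchanged groups that shared a simulated LPS group gave 0.499 and 0.470. Splitting the LPS arrays between the inhibitors gave a mean r of 0.537 (0.426 to 0.615 over 20 splits). Unchanged groups split alike gave a mean of 0.00131. Their number deviations were the same in every group and cancelled, so this value and their shared genes below were bound to be near 0. They cannot show whether LPS responses that differ by number add to the 0.537. The covariance was 0.0660, against 0.0101 simulated and 0.0595 with split arrays. Both inhibitors lowered 158 genes, of 273 and 453, where independent lists would share 6.71. They raised 99, of 262 and 219, where such lists would share 3.11. Simulated unchanged groups shared a mean of 0.05 genes over 20 runs, counted without regard to direction. Hardly any gene passes the threshold in unchanged groups, so this mean was bound to be near 0. It cannot show how much the shared LPS arrays add to the overlap of changed genes. With the replicate block 530 were lowered by both, of 978 and 1345, and 552 raised, of 1253 and 946, where independent lists would share 71.4 and 64.3. With split LPS arrays a mean of 93.0 (13 to 188) were lowered and 78.3 (2 to 227) raised by both, with means of 6.14 and 6.11 for independent lists and 0 each way for unchanged groups split alike.

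Without LPS the Tpl-2 inhibitor raised cholesterol synthesis genes. MSMO1 went from 7.81 ± 0.81 to 10.09 ± 0.46 (log2 fold change 2.27, SE 0.37, adjusted p = 0.00475). SQLE, squalene epoxidase, rose by 1.97, SC5D by 1.46, HMGCS1 by 1.10, IDI1 by 1.08 and SREBF2, a transcription factor of sterol synthesis, by 0.74. MYLIP fell from 9.19 ± 0.22 to 8.15 ± 0.31 (-1.04). These 7 genes, 6 up and 1 down, were all of the 18435 genes that changed, with adjusted p from 9.21e-07 to 0.0108. Adding the replicate block gave 26 genes, 23 up and 3 down, and leaving out the fifth untreated array gave 11. Without 1 of the replicate numbers MSMO1, HMGCS1 and SREBF2 lost the call (adjusted p up to 0.154, 0.160 and 0.612), while SQLE, SC5D, IDI1 and MYLIP did not. Those fits did not pair the arrays. With all numbers and the block, the adjusted p was 4.58e-08 for MSMO1, 0.000154 for HMGCS1 and 0.00332 for SREBF2. Of 16 genes of cholesterol synthesis and uptake 5 rose and 0 fell (13 and 0 adjusted over the list alone, 9 and 0 with the block), with a median of 0.72. The camera adjusted p was 1.37e-75, and 7.06e-10 with an estimated correlation, and the list mean was higher with the inhibitor in 5 of 5 same-numbered pairs. MYLIP was the 1 of 11 lipid efflux and LXR target genes that changed, or 4 rose and 3 fell adjusted over the list alone. With the block 2 rose, ACACA (0.92) and FASN (0.62), and 3 fell, ABCG1 (-1.80), ABCA1 (-1.43) and MYLIP. That list, whose members went both ways, did not pass. The interferon list had a median of -0.44 (adjusted p = 1.17e-11, and 0.638 with an estimated correlation) and the lysosome list one of 0.13 (adjusted p = 0.000725, and 0.601 with an estimated correlation), with 0 members changed in either, also adjusted over the list alone. Chemokines (-0.14), ERK output (-0.10) and heat shock genes (-0.15) passed with the block only, at adjusted p = 0.0160, 0.0190 and 0.00972, the values in brackets being medians.

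The MEK inhibitor changed 0 genes without LPS by limma, with 138 genes at an unadjusted p under 0.05 (284 with the replicate block). Adding the replicate block gave 1 gene, EGR3 (-1.82), and the other fits without the block, including those that left out arrays, gave 0. As a list, ERK output genes were lower (median -0.17, camera adjusted p = 8.84e-09, and 0.0276 with an estimated correlation), with 0 of 28 changed, or 2 lower adjusted over the list alone and 1 with the block. Chemokines were lower too (median -0.24, adjusted p = 0.000185, and 0.0276 with an estimated correlation, which became 0.0510 with the block), with 0 of 26 changed, also adjusted over the list alone. Neither list passed fry (adjusted p = 0.502 for both). The NF-κB list had a median of -0.12 (adjusted p = 1.92e-06, 0.144 with an estimated correlation, and 0.0441 with the block added). The ATF4 list had one of -0.08 (adjusted p = 0.0119, and 0.656 with an estimated correlation). With the block only, inflammatory cytokines (median 0.01, mean -0.13) and the protease list (median -0.10) passed, at adjusted p = 0.0253 and 0.0234, and the protease list also with an estimated correlation and the block (adjusted p = 0.0443). Adjusted over the list alone 1 of the 28 cytokines was lower. The cholesterol list did not pass, with a median of -0.02 and a mean of 0.01.

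Compared directly without LPS, 9 genes differed between the inhibitors, 7 higher and 2 lower with the Tpl-2 inhibitor (26 with the replicate block, 21 and 5). MSMO1 (2.38), SQLE (2.05), SC5D (1.51), IDI1 (1.09), HMGCS1 (0.98) and SREBF2 (0.90) were higher, and GPR82 (-1.32) and MYLIP (-1.07) were lower. The level of GPR82 with the Tpl-2 inhibitor, 3.23, lay below that under which 10% of genes lay (3.31). Calls of MSMO1, HMGCS1 and GPR82 were lost without 1 of the replicate numbers (adjusted p up to 0.0861, 0.407 and 0.226). Of the 16 cholesterol genes 5 were higher and 0 lower (14 and 0 adjusted over the list alone), with a median of 0.61. The camera adjusted p was 1.31e-78, and 4.69e-10 with an estimated correlation. At the preset correlation the interferon list was lower with the Tpl-2 inhibitor (median -0.42, adjusted p = 0.480 with an estimated correlation) and 4 lists were higher: NF-κB targets (0.15, 0.178), ATF4 (0.12, 0.432), lysosome (0.13, 0.432) and ERK output (0.10, 0.432), the values in brackets being the median and that adjusted p. MYLIP was the 1 LXR target that differed, or 4 were higher and 4 lower adjusted over the list alone and 2 and 3 with the block. LXR targets (median -0.10), heat shock genes (-0.09) and MAPK phosphatases (0.12) passed with the block only, at adjusted p = 0.0170, 0.0426 and 0.0175.

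**Figure D4:**
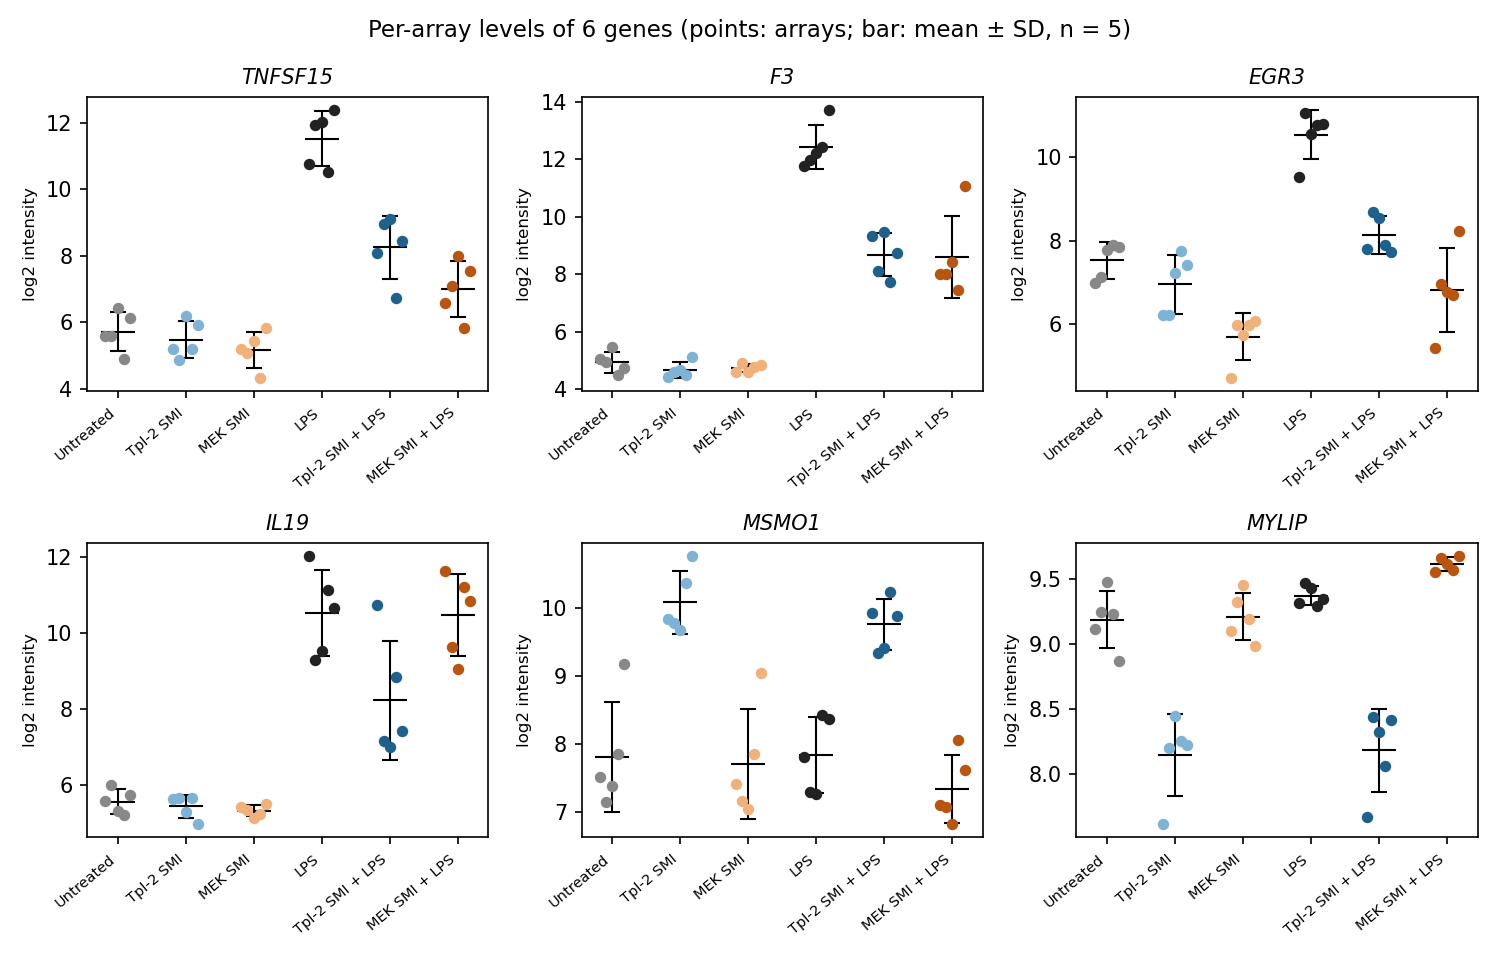
Log2 intensity (vertical axes) of TNFSF15, F3, EGR3, IL19, MSMO1 and MYLIP in the 6 groups; points are arrays and bars the mean ± SD of 5. IL19 stood at 8.22 with the Tpl-2 inhibitor and LPS against 10.47 with the MEK inhibitor and LPS, a difference whose call several alternatives ended, and MSMO1 stood at 10.09 with the Tpl-2 inhibitor without LPS and 9.77 with it.

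Whether LPS changed the effect of an inhibitor was tested as an interaction. The Tpl-2 inhibitor's effect differed in 36 genes, 7 upward and 29 downward, and the MEK inhibitor's in 74, 16 upward and 58 downward. With the Tpl-2 inhibitor the differences were largest for TFPI2 (-4.29), IL24 (-3.83), F3 (-3.48), TNFSF15 (-3.03), SCG5 (-2.35) and CSF3 (-2.27), and upward for RARRES1 (2.66), GPC4 (2.01), TBC1D9 (1.05), KDM2B (0.93), PRR34-AS1 (0.91) and MYH10 (0.88). With the MEK inhibitor they were TFPI2 (-4.30), TNFSF15 (-3.97), F3 (-3.64), SCG5 (-2.90), DUSP6 (-2.82) and SOWAHC (-2.38), and upward GPC4 (2.04), C22orf42 (1.84), RND1 (1.66), GPC3 (1.56), NECTIN2 (1.39) and TBC1D9 (1.34). Over these 12 genes each the adjusted p ran from 0.0145 to 0.0449 and from 0.000331 to 0.0439. TFPI2 stood at 3.38 in untreated, 3.43 in Tpl-2 SMI and 3.24 in MEK SMI cells without LPS, SCG5 at 3.29 and RARRES1 at 3.09 in untreated cells, near or below the level under which 10% of genes lay (3.31). A fall without LPS was thus hardly measurable for these genes, and the size and order of their differences are open. Without 1 of the replicate numbers all 12 genes named for the Tpl-2 inhibitor and 10 of the 12 for the MEK inhibitor lost the call. The replicate block gave 464 genes, 213 upward and 251 downward, and 777 genes, 299 upward and 478 downward. For the Tpl-2 inhibitor 20 genes differed without the third Tpl-2 SMI array, 22 without the fourth and 18 without the fifth Tpl-2 SMI + LPS array. For the MEK inhibitor 49 did without the first MEK SMI + LPS array, 48 without the second and 47 without the third MEK SMI array, and 144 without the fifth MEK SMI + LPS array. The difference for cholesterol genes with the Tpl-2 inhibitor (median -0.28, camera adjusted p = 9.14e-06) had adjusted p = 0.0566 with an estimated correlation, as did ERK output (-0.35) and the MAPK phosphatases (-0.39). In these lists 1 gene (STARD4, -1.87), 0 and 0 differed, all downward, or 4, 4 and 3 adjusted over the list alone and 3, 3 and 2 with the block. No list passed an interaction with an estimated correlation. At the preset one the interferon list did with both inhibitors (medians 0.81 and 0.77; adjusted p = 0.517 and 0.723 with an estimated correlation), as did inflammatory cytokines (-0.49 and -0.23; 0.129 and 0.692) and ATF4 genes (-0.28 and -0.24; 0.253 and 0.723). Of the 28 cytokines 3 and 1 differed downward, or 6 and 3 adjusted over the list alone, as with the block, which added 1 upward for each. Of the 36 interferon genes 0 differed, or 1 and 2 upward with the block. NRF2 genes passed with the Tpl-2 inhibitor (-0.36; 0.505), and ERK output (-0.38; 0.310) and NF-κB targets (0.31; 0.692) with the MEK inhibitor. With the block only, metallothioneins passed for both (adjusted p = 0.0195 and 0.000129), and MHC class II and protease genes for the Tpl-2 inhibitor (adjusted p = 0.00901 and 0.0195).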

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

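All tests in this part were chosen before their results were seen. The inhibitor effect differed with and without LPS in 36 genes for the Tpl-2 inhibitor and 74 for the MEK inhibitor. Among the named genes of the LPS comparisons, 7 of 24 differed for each inhibitor, or 21 and 24 with the replicate block. For the Tpl-2 inhibitor the difference between its effect with and without LPS was 2.66 for RARRES1, 2.01 for GPC4, -4.29 for TFPI2, -3.83 for IL24, -3.48 for F3, -3.03 for TNFSF15 and -2.35 for SCG5. For the MEK inhibitor it was 2.04 for GPC4, 1.84 for C22orf42, -4.30 for TFPI2, -3.97 for TNFSF15, -3.64 for F3, -2.90 for SCG5 and -2.82 for DUSP6. Without LPS, TFPI2, SCG5 and RARRES1 lay near the level under which 10% of genes lay (3.31), which leaves the size of their differences open. The splits used another fit, of the differences between same-numbered arrays, taken apart with and without LPS. It takes out the replicate number and also LPS responses that differ by number, which the replicate block leaves in. Its spread was estimated from these differences alone. Its counts are therefore not those given above, nor the 464 and 777 of the replicate block. In it the real split gave 1369 and 1902 genes for the 2 inhibitors, against at most 0 and 1 in the other splits. For each, 1 of 100 splits gave as many, a share under 0.05, over splits that ignore the replicate numbers.

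A single array stood apart from its group in 4 of 66 sets of 5 arrays tested for genes whose levels are given, by the gap to its neighbour over the group's range against Dixon's 95% critical value. Chance puts about 1 in 20 groups past it, here 3.3. They were TFPI2 in the fifth MEK SMI array (0.736) and ENPP2 in the fifth arrays of the untreated (0.748), LPS (0.899) and MEK SMI + LPS (0.870) groups. The ENPP2 array was the highest of its group without treatment and the lowest in the other 2 groups.

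Of 1410 probe sets without a single gene symbol, which entered no comparison above, 600 changed with LPS, 327 up and 273 down. With LPS, 44 of them changed with the Tpl-2 inhibitor and 43 with the MEK inhibitor. Without LPS, 4 changed with the Tpl-2 inhibitor and 0 with the MEK inhibitor, and 4 differed between them.

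Regrouping the arrays without regard to the replicate numbers gave a count as large as the real one in 1 of 100 splits, the real one, in several comparisons. These were LPS against untreated cells (8677 genes, highest other 3707) and the Tpl-2 inhibitor in LPS (535, 70). The Tpl-2 inhibitor without LPS (7, 4) and the inhibitors against each other without LPS (9, 2) did the same. That share is under 0.05, over splits that ignore the pairing. The LPS-induced genes lowered by the Tpl-2 inhibitor (133, 17) and by the MEK inhibitor (143, 108) gave the same share. They were picked for high LPS arrays, which favours the real split in advance, so no conclusion is drawn from it. For the MEK inhibitor in LPS 3 of 100 splits gave as many as the real 672 (highest other 823) and for the direct comparison in LPS 2 of 100 (156, highest other 256), also under 0.05 of such splits. The split with 823 genes parted 3 of the 5 same-numbered pairs and the one with 256 parted 1, so they partly compared replicate numbers. Among the 16 splits that part all 5 pairs, as the real one does, the highest other counts were 2 and 0 for these comparisons, or 106 and 14 with the replicate block, but for any comparison 16 splits are too few for a share under 0.05. For the MEK inhibitor without LPS the real count was 0, which any split reaches (100 of 100, highest other 16), so the splits decided nothing. With the block the real count was 1 and the highest other of the 16 splits 0.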

How the results depend on the processing

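The fits that left out a replicate number with the block kept, the median centring of gene lists and the alternatives for the genes named by class were chosen after seeing the data. Under the replicate block 2231 genes changed with the Tpl-2 inhibitor in LPS, 2291 with the MEK inhibitor, 1253 in their direct comparison, 26 with the Tpl-2 inhibitor without LPS, 1 with the MEK inhibitor, 26 between the inhibitors without LPS, and 464 and 777 in the interactions of the Tpl-2 and MEK inhibitors. It gave 309 LPS-induced genes lowered by the Tpl-2 inhibitor and 288 by the MEK inhibitor. Every gene called without the block was called with it, and apart from the gene and list calls given with their results it changed no other camera call of a list and no other call of a named gene in its comparison. With only the compared groups in the fit, which leaves fewer degrees of freedom, the counts were 140, 249 and 7 in LPS, 4 for the Tpl-2 inhibitor without LPS, 20 for its interaction, and 54 and 71 for the LPS-induced genes lowered by the Tpl-2 and MEK inhibitors. Choosing LPS-induced genes on replicates 1 and 2 and testing the rest gave 65 and 57 of 840 (7.74% and 6.79%), with fewer arrays in each step, and a log2 fold change of at least 2 gave 68 and 63 of 379 (17.9% and 16.6%), with fewer genes. Testing all probe sets gave 11 probe sets for the Tpl-2 inhibitor without LPS and 15 between the inhibitors. In each case 4 of them had no single gene symbol. Array weights gave 17 and 16 genes for these comparisons and 172 for the MEK interaction. The arrays numbered 5 had weights from 0.298 to 0.835, the lowest of all being that of MEK SMI + LPS. Some arrays of other numbers also lay below 0.835. Leaving out number 5 without weights gave 15, 12 and 132 genes. Whether the low weights of number 5 account for the counts was not tested further. Splitting the LPS arrays lowered the correlation of the inhibitor effects to a mean of 0.537, and an estimated correlation left 13 of 55 list calls. Leaving out arrays or replicate numbers gave 6890 to 8714 genes for LPS, 163 to 606 for the Tpl-2 inhibitor in LPS, 248 to 920 for the MEK inhibitor, 24 to 208 for the direct comparison, 4 to 15 for the Tpl-2 inhibitor and 0 in all fits for the MEK inhibitor without LPS, and 5 to 12 between them. It gave 4 to 43 and 18 to 144 for the Tpl-2 and MEK interactions, 60 to 157 and 73 to 165 for the LPS-induced genes lowered by each, and correlations of 0.668 to 0.719. With the block kept, leaving out a number gave 1209 to 2038 and 1471 to 2579 genes for the inhibitors in LPS and 406 to 1094 between them, 9135 to 9974 for LPS, 12 to 19 and 0 to 3 for the Tpl-2 and MEK inhibitors without LPS and 13 to 31 between them, and 117 to 413 and 359 to 969 for the interactions. The LPS count stayed within 1.5 times under all 9 alternatives (6107 to 10467). Of the 135 named results none turned sign under the settings named here; 5 lost the call when quantile normalized again, 6 with array weights, 2 with trend and robust options and 21 to 62 without 1 replicate number, while the filter on dim genes left 103 to test, all still called. Of the 252 list tests, fry ended 26 calls and added 11. The filter on dim genes, which left 243 tests and too few erythroid markers to test, ended 5 (MHC class II with the Tpl-2 inhibitor in LPS, metallothioneins and proteases with the MEK inhibitor, ATF4 and cytokine genes in its interaction) and added 15. Quantile normalization ended 2 (interferon in the direct comparison in LPS and ATF4 in the MEK interaction) and added 2, and median centring added 4. Of 55 called list medians 0 turned sign on rescaling. Low signal near background limits small changes of dim genes.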

Other observations

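The tests of other cell types, of MEK, of IFNB1 and of the dose below, the use of median centring on gene lists and the choice of LPS-lowered genes on part of the replicates were decided after the main results were seen. Among the 1830 genes that fell at least 2-fold with LPS, 87 were raised by the Tpl-2 inhibitor, 43 by the MEK inhibitor and 28 by both, while 1 and 23 were lowered further. Under the replicate block 438 and 178 of 1869 were raised, 140 by both, and 20 and 100 lowered. Genes picked for low LPS arrays and set against the same arrays favour rises, so 1203 were also chosen on replicates 1 and 2 and tested on 3 to 5, where 25 and 8 were raised (2.08% and 0.665%), 7 by both, against 47 and 11 of 2075 (2.26% and 0.530%) chosen and tested on 3 to 5. With the block these numbers were 246 and 65 of 1459 (16.86% and 4.455%), 54 by both. Chosen and tested on 3 to 5 with the block, 353 and 79 of 2189 were raised (16.13% and 3.609%). Interferon response genes had a higher list mean with each inhibitor in LPS in 5 of 5 same-numbered pairs, and a lower one with the Tpl-2 inhibitor without LPS in 5 of 5.

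Markers of other blood cells, except those of dendritic cells, varied more between replicate numbers than between treatments. The mean of the T cell markers ranged over 3.18 log2 units between numbers and 0.27 between groups, that of the platelet markers over 2.34 and 0.18, and that of the NK cell markers over 2.11 and 0.41. Dendritic cell markers ranged over 0.44 between numbers and 0.78 between groups.

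The cholesterol list was higher with the Tpl-2 inhibitor without LPS (median 0.72). The list's median was at least 0.66 after quantile normalization again and median centring. Both rescaled values that were already normalized, so they cannot decide on the authors' normalization. The highest median of a marker list of another cell type was 0.155, and with the MEK inhibitor the cholesterol list had a median of -0.0154. These medians argued against RNA of other cells and loss of MEK signalling as the whole cause. ABCA1 (-1.43) and ABCG1 (-1.80), which export cholesterol, were lower with the block, and neither passed without it. Whether the rise runs through Tpl-2 or another target of the compound was not tested and stays open.

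The interferon list was higher with the MEK inhibitor in LPS (median 0.70), a call that an estimated correlation ended. Its median was at least 0.68 on rescaling, which cannot undo the authors' normalization and so decided nothing on it. The highest marker list median was 0.0670. The highest marker list mean, of dendritic cells and higher in 5 of 5 pairs, was 0.15, against 0.76 for the interferon list. These values argued against RNA of other cells. A candidate explanation is more interferon beta, but IFNB1 was 0.49 higher (SE 0.21, adjusted p = 0.147 with the block), with an upper 95% bound of 0.93, and its level was 3.99 with LPS and 4.09 in untreated cells, where 10% of genes lay below 3.31, so the arrays could not decide.

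Of the 8 ERK output genes lowered by the MEK inhibitor in LPS, 6 were lowered less by the Tpl-2 inhibitor, with a median ratio of the effects of 0.660 and a median direct difference of 0.86. The 8 were taken for their fall with the MEK inhibitor, which by itself favours a ratio under 1, and over all 28 ERK output genes the direct difference did not pass (median 0.06, adjusted p = 0.317). SPRED1 differed by the direct test, a call lost with array weights (adjusted p = 0.0684) and without replicate number 2, 3, 4 or 5 (adjusted p from 0.0851 to 0.240), and with the block EGR1 (adjusted p = 0.00183) and EGR3 (adjusted p = 0.00397) did too. The median difference was at least 0.829 after quantile normalization again and without dim genes. The filter leaves the values of the kept genes unchanged, so it showed only that the median did not rest on dim members. Quantile normalization of values already normalized cannot decide on the authors' normalization. The Tpl-2 inhibitor dose may have blocked the pathway less than the MEK inhibitor dose, or part of the signal to MEK may bypass Tpl-2, and with 1 dose each these cannot be told apart.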
